A study of Arabidopsis thaliana with 2 samples.

How the data were processed

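Total RNA from 2 hypocotyl samples was labelled as biotinylated cRNA and hybridised to Affymetrix ATH1 arrays, 1 array per sample and 1 colour, per the labels. The deposited values are linear probe set intensities, with 1 decimal, for 22810 probe sets on each array. The software that made them is not given in the sources used here. From the values, the authors' scaling brought both arrays to a mean of 100 after trimming 2% at each end, and the median intensities were 42.0 and 42.7. No value was below 0. Per the labels, the average background was 79.94 on the array of sample 1 and 95.57 on that of sample 2, the average noise was 4.81 and 6.28, and 586 and 974 cells were marked as outliers. Each of 3 control transcripts has 2 series of probe sets, and the ratio of the 3' to the 5' probe set differed between them. For actin it was 8.45 in sample 1 and 6.55 in sample 2 in the first series, and 1.34 and 1.29 in the second. For ubiquitin it was 1.82 and 1.85 in the first and 1.43 and 1.41 in the second, and for GAPDH 1.16 and 1.14, and 1.21 and 1.32.

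Samples were grouped from the organism part in the labels, which gives both the same group. Values were rescaled to the same trimmed mean, by factors very close to 1 on both arrays. The 64 control probe sets were left out of counts and lists. A probe set was called above the limit on an array when its signal exceeded the highest signal among the TrpnX control probe sets, which target a bacterial transcript; no Mur control probe sets were in the table. The log2 ratio is log2 of sample 2 minus log2 of sample 1, with nothing added, over probe sets above the limit on both arrays. No test was run, as 2 samples of 1 group give no contrast.

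Probe sets were named through the platform annotation, with symbols updated by gene identifier through the RefSeq gene table of the TAIR10.1 assembly. Of 14016 probe sets in the annotation, 13513 had 1 gene and 503 had several, and 13436 of the first kind matched the gene table. A further 8730 plant probe sets were unnamed here. No probe set with several genes was named, and no coordinates are given because no build is named for the values.

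Lists of 278 genes in 19 groups were fixed by locus before the data were examined, and 31 members in 15 groups could be measured. A list of 3 or more members was described by its median log2 ratio and that median's percentile among 10000 random lists of the same size, drawn from the same 10 bins of mean signal. The percentile describes these arrays and is no p-value. A further 19 lists of gene families and organelle genes were chosen once it was known which symbols could be named, but before their members' values were looked at. Genes were named by a rule fixed beforehand. It takes every measured member of the secondary wall, xylan, lignin and xylem death lists, and up to 4 members of every other list plus any that differed by 2-fold. It also takes the 10 largest differences in each direction among single-gene probe sets with mean signals of at least 4 times the mean limit, and the 10 with the highest mean signals. A second set of largest differences, with mean signals of 100 or more, was added after seeing the data.

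The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated arrays of 19379 probe sets with the observed mean signals. Their normal noise was scaled to the median absolute deviation of the log2 ratio in 10 bins of signal. That deviation was 0.242 over all these probe sets, against an SD of 0.391, so the results below hold for narrower noise than the arrays showed. For sample 2 against sample 1, all of the 100 simulated 3-fold changes and all of the 100 simulated 4-fold changes at mean signals over 50 were recovered at 2-fold or more, and 95.3% of 1000 unchanged lists of 12 members fell inside the central 95%. Of the first 100 of these lists, 89 did, and the number drawn was raised to 1000 after that count was seen. Alternatives were no rescaling, scaling to the same median, quantile normalization, loess normalization with a span of 0.3, other detection limits, probe sets with plain names alone, adding 16 before log2, thresholds of 1.5-fold and 3-fold, and leaving out each sample.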

Results

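Transcript levels were measured in 2 samples of Arabidopsis thaliana hypocotyls, the stem below the seed leaves, which thickens by secondary growth in older plants and lays down xylem with lignified, xylan-rich walls. The plants were of the Col ecotype, were at growth stage 6.0 and were kept at 22 °C with 8 h of light and 16 h of darkness on compost and vermiculite. Each sample was hybridised to its own ATH1 array, which carries 22810 probe sets, and 22746 of these target plant transcripts and not controls. The labels give both samples the same tissue, ecotype and conditions, so there is 1 group and no contrast between conditions. What the design allows is a description of the transcripts detected in hypocotyls and of how closely the samples, called sample 1 and sample 2 here, matched. The labels do not say whether the samples came from separate plants, so the spread between them may be technical. With 2 arrays no test was possible, and values are given as the mean scaled signal ± SD (n = 2) or as the log2 ratio of sample 2 over sample 1. The number of arrays limits the precision. Signals of different probe sets cannot be set against each other, since probes differ in how brightly they report the same amount of RNA.

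Genes that make secondary wall xylan were detected in both samples. GUT2, also known as IRX10, and its close relative GUT1, both xylan backbone xylosyltransferases, had mean signals of 173 ± 18.5 and 139 ± 16.9 (SD, n = 2). IRX15 and IRX15-L, which are needed for normal xylan in secondary walls, had 79.3 ± 12.7 and 240.4 ± 22.3. All 4 measured members of the 14-member xylan synthesis list were above the detection limit on both arrays. So were 85.2% of all plant probe sets, and random lists of that size had a median of 4, so this count does not set the list apart. Their median log2 ratio was 0.20, at percentile 96.9 of 10000 random lists matched on signal, inside the central 95%. GUT1 was the member with the lower signal in sample 2, at a log2 ratio of -0.25. Of the 20 lignin genes listed, 2 were measured. HCT, the hydroxycinnamoyltransferase of the lignin precursor pathway, had a mean signal of 1505 ± 99.0. PRX72, a cell wall peroxidase linked to lignin polymerisation, was close to the limit, with 4.2 in sample 1 and 8.4 in sample 2. No member of the lists for secondary wall cellulose, secondary wall regulators, xylem cell death, or suberin and periderm had a named probe set here, so nothing is said of those processes.

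Genes that act in the cambium and in vascular patterning were also detected, and the log2 ratios of the measured members lay between -0.16 and -0.05. CLE41 and CLE44, which encode the same peptide signal from phloem to cambium, had mean signals of 728 ± 41.0 and 73.8 ± 5.80. MOL1, a receptor-like kinase of the cambium, had 264 ± 5.80, and PHV, a homeodomain transcription factor that patterns vascular tissue, had 222 ± 7.07. All 4 measured members of this 17-member list were above the limit on both arrays, where random lists of that size also had a median of 4. The members' median log2 ratio of -0.09 lay at percentile 18.3 of matched random lists. Of 16 phloem genes, OPS, which acts in phloem differentiation, had a mean signal of 39.0 ± 6.29. The sucrose exporter gene SWEET11 had 32.5 ± 5.80.

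**Figure D1:**
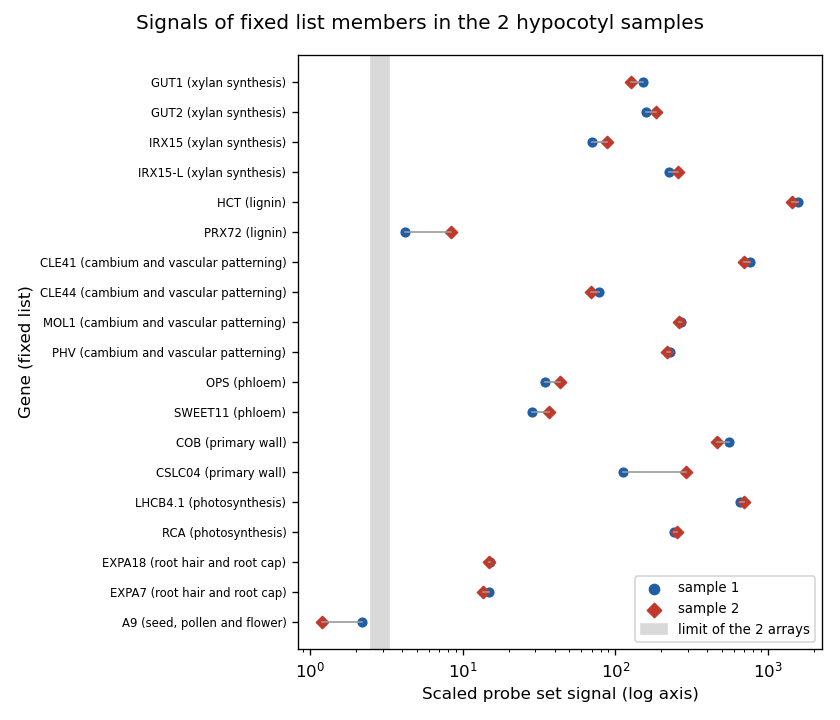
Scaled probe set signal on a log axis (horizontal) for 19 measured members of 8 gene lists (vertical), with a circle for sample 1 and a diamond for sample 2, joined by a line; the grey band spans the detection limits of the arrays, 2.5 and 3.3. The xylan and cambium genes lie far to the right of the band in both samples, A9 lies to its left, and CSLC04 has the widest gap among members with signals above 100, from 111.9 to 289.

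The primary wall genes measured went different ways. CSLC04, which makes the glucan backbone of xyloglucan, had a signal of 111.9 in sample 1 and 289 in sample 2, a log2 ratio of 1.37. COB, needed for oriented cellulose deposition in expanding cells, had 553 and 465, a log2 ratio of -0.25. Among measured members of the lists fixed beforehand with both signals above the brightest Bacillus controls, CSLC04 was the one that differed between the samples by more than 2-fold. Lists with 2 measured members were not ranked against random lists.

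Genes typical of other tissues and states were measured too, each described on its own. The photosynthesis genes RCA, the activase of Rubisco, and LHCB4.1, a light-harvesting protein, had mean signals of 247 ± 6.36 and 674 ± 29.3. The root hair expansin genes EXPA7 and EXPA18 had 14.2 ± 0.920 and 15.1 ± 0.140, above the limit. These signals were little above the brightest Bacillus controls, 13.1 and 12.6, so they are weak evidence of expression. The anther gene A9, the measured member of the 24-member list for seed, pollen and flower, was below the limit on both arrays, at 2.2 and 1.2. AUR1, a mitotic kinase, had 51.0 ± 1.34, and the clock gene GI had 124.7 ± 2.90. The flavonoid gene DFR had 23.5 ± 0.570.

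Genes that respond to touch, wounding and cold were detected as well. CML38, a calmodulin-like gene, had a signal of 279.9 in sample 1 and 417 in sample 2, a log2 ratio of 0.57. The zinc finger gene STZ, also induced by many stresses, had a mean of 1213 ± 72.5 and a log2 ratio of 0.12. The cold-regulated genes COR47 and COR15B had log2 ratios of -0.34 and 0.32. COR15A had 14.6 and 7.7, the second value below the brightest Bacillus control on that array, 12.6. The median of the 3 lay at percentile 2.52 of matched random lists, just inside the central 95%. It lay outside at 2 times the limit (2.34) and after adding 16 before log2 (0.45), and inside after quantile (3.94) and loess (3.68) normalization. The defensin gene PDF1.2, the measured member of the defence list, had 10.8 and 3.40, both below the brightest Bacillus controls, 13.1 and 12.6. The reference genes SAND, TIP41L and PEX4, often used because their levels vary little, had log2 ratios of -0.15, -0.38 and -0.08.

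Across the lists fixed before the data were examined, 31 of 278 members had a named probe set, and 30 of these were above the limit on both arrays. With stricter limits, 28 passed at 2 times the limit, 27 with the brightest Bacillus controls and 21 at a signal of 50. At the main limit, random lists of that size held between 22 and 30 such probe sets in the central 95% of draws, with a median of 27. None of the 4 fixed lists with at least 3 measured members had a median log2 ratio outside the central 95% of matched random lists. The lists were thinly covered, and a list's value stands for its named members alone.

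Among all plant probe sets, 20098 were above the limit in sample 1 and 19894 in sample 2, and 19379 (85.2%) in both. This limit is the highest signal among the few TrpnX control probe sets alone, which target a bacterial transcript, and it was low, 2.5 and 3.3. With so few controls it is a weak bound on background. Other Bacillus control probe sets reached 13.1 and 12.6. With the highest signals of all Bacillus controls as the limit, 15919 probe sets (70.0%) passed on both arrays. With a signal of 50 on both arrays as the limit, 10251 probe sets (45.1%) passed. Both of these limits were chosen after seeing the data. The 10 single-gene probe sets with the highest mean signals included PRXR1, a peroxidase, with 3378 ± 486, GAPC2, a cytosolic glycolytic dehydrogenase, with 2464 ± 303, and UBC28, a ubiquitin-conjugating enzyme, with 2601 ± 367. AT3G49910, AT4G34670 and AT5G20290, which encode ribosomal proteins, and AT1G01100, an acidic ribosomal protein gene, had means of 2918 ± 434, 2601 ± 321, 2533 ± 395 and 2398 ± 271. AT5G19510, an elongation factor subunit gene, AT1G51200 and AT1G78040 completed the set with 2433 ± 225, 2426 ± 338 and 2564 ± 383. All 10 had lower signals in sample 2, by log2 ratios from -0.32 to -0.19. The 407 probe sets with mean signals of 1000 or more had a median log2 ratio of -0.15 as a whole.

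The samples matched closely over the probe sets above the limit on both arrays. Across these probe sets, which are not independent replicates, Pearson's r of the log2 signals was 0.981 and Spearman's rho 0.986. The SD of the log2 ratio was 0.391 and its scaled median absolute deviation 0.242. The spread narrowed with signal, from an SD of 0.633 for mean signals under 20 to 0.217 between 100 and 200 and 0.125 at 1000 or more. The samples' values were not copies of each other, since 329 of the 22746 plant probe sets had identical values at the 1 decimal given.

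At 2-fold or more, 453 probe sets had higher signals in sample 2 and 176 in sample 1. Quantile normalization changed that split to 342 and 245. The main limit was lower for sample 1 (2.5) than for sample 2 (3.3), so dim probe sets low in sample 1 passed more readily. That favours counts toward sample 2. With the limit from the seed, pollen and flower list the counts were 509 and 466. That limit was the signal of A9, 2.2 in sample 1 and 1.2 in sample 2, so it favours counts toward sample 1 instead. With the brightest Bacillus controls, 13.1 and 12.6, the counts were 51 and 23, and with an equal limit of 50 they were 20 and 7. The imbalance is therefore not explained by unequal limits alone. Of the 629 probe sets at the main limit, 588 had mean signals under 50, where the spread is widest, and 393 had 1 named gene. In the simulated arrays, 331 unchanged probe sets also differed by 2-fold or more, and none of them had a mean signal of 50 or more. Their normal noise was scaled to the median absolute deviation, which is narrower than the SD (0.167 against 0.207 at a signal of 50 on both arrays). Such noise rarely gives bright 2-fold differences, so their absence does not show that the 41 observed at mean signals of 50 or more exceed noise. The largest differences by the rule fixed beforehand were mostly of dim probe sets. Toward sample 2 they were AT1G33760, which encodes a transcription factor of the ERF family, with 4.90 and 44.0, AT1G50040 with 14.4 and 65.4, and AT3G45680 with 8.40 and 35.7. AT2G41090, a calmodulin-like gene, had 7.20 and 29.6, and the cation exchanger gene CHX16 had 4.1 and 19.8. AT3G49770, AT5G60260, AT5G61400, AT1G52530 and AT2G32030 completed the set. For 9 of these 10 genes, all but AT1G50040, the signal in sample 1 was no higher than that of the brightest Bacillus control on that array, 13.1, so the size of the ratio and the order of these genes are not given. Toward sample 1, those with both signals above the brightest Bacillus controls were AT4G33550 with 163 and 35.4, AT2G37870 with 505 and 174, and OCT1, a carnitine transporter gene, with 383 and 132.7. The other 7, CXE20, AT4G17410, AT5G17670, AT5G56880, AT5G57650, AT2G40260 and AT4G13450, had signals in sample 2 no higher than the brightest Bacillus control there, 12.6, and mean signals of 22.0 or less.

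Among single-gene probe sets with mean signals of 100 or more, a limit chosen after seeing the data, the largest differences toward sample 2 included CSLC04, EXO, a brassinosteroid-responsive gene that promotes growth, with 329 and 697, and the expansin-like gene EXLA2, with 73.4 and 155. The calmodulin-like gene CML37 had 87.5 and 167, and the glutaredoxin gene GRX480 had 103.8 and 207. AT2G41640, AT3G02840, AT3G19680, AT1G77640 and AT3G27540 had log2 ratios from 1.02 to 1.44. Toward sample 1 they were AT2G37870 and OCT1, with log2 ratios of -1.54 and -1.53, then AT1G48750, a lipid transfer protein gene, with 848 and 389. The ubiquitin ligase gene PUB19 had 194 and 102, and the dehydrin gene LTI30 had 127 and 74.7. AT5G10580, AT1G49310, AT1G26920, AT4G34600 and AT1G64360 had log2 ratios between -0.91 and -0.75. These differences are between label-identical samples and carry no replicate check.

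**Figure D2:**
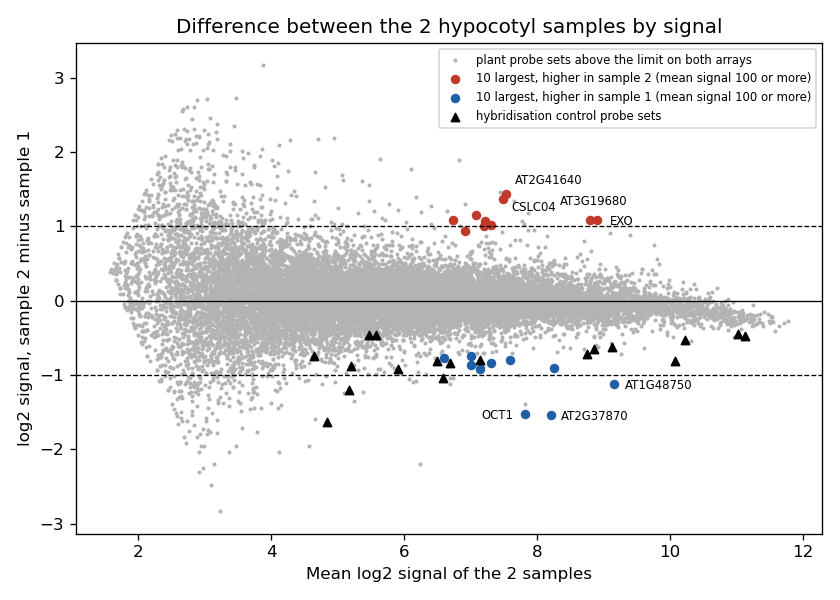
The log2 ratio of sample 2 over sample 1 (vertical) against the mean log2 signal of both samples (horizontal) for the 19379 plant probe sets above the limit on both arrays, with dashed lines at 2-fold, coloured circles for the 10 largest differences in each direction among single-gene probe sets with mean signals of 100 or more, and triangles for 18 hybridisation control probe sets. The spread is widest on the left, the brightest probe sets lie below 0, and all 18 triangles lie below 0.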

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

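The limits from all Bacillus controls (13.1 and 12.6) and from a signal of 50 were chosen after seeing the data. The counts of 2-fold differences depended on how dim a probe set was allowed to be. Higher in sample 2 and in sample 1, they were 203 and 70 at 2 times the limit, 51 and 23 with all Bacillus controls, 20 and 7 at a signal of 50, and 26 and 8 after adding 16 before log2. A limit from the seed, pollen and flower list, which rests on 1 probe set, gave 509 and 466. The imbalance between the directions was then small, but that limit was higher for sample 1 (2.2) than for sample 2 (1.2), which favours counts toward sample 1. At 1.5-fold there were 1234 and 714, and at 3-fold 129 and 33. Without rescaling, 465 were higher in sample 2, because ratios of exactly 2 then count. More probe sets were higher in sample 2 under each of these settings. The SD of the log2 ratio was 0.260 with all Bacillus controls, 0.207 at a signal of 50, 0.210 after adding 16 and 0.661 with no limit. At a signal of 50, 10251 probe sets were above the limit on both arrays. From either sample alone, between 19894 and 20098 probe sets and 30 to 30 list members were above the limit. At 2 times the limit, and after adding 16, 1 fixed list, that for heat, cold and drought, fell outside the central 95%. Of the list medians under the alternatives, 235 moved by less than the spread of random lists and 10 by more. All 390 recomputed gene levels stayed within 1 SD, as those from a single sample must by construction. A limit from the Mur controls could not be run, as the table holds none. No paired analysis was possible because there was 1 group. Signal over background sets what can be read: under a mean signal of 20 the SD of the log2 ratio was 0.633.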

Other observations

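The lists in the first 2 paragraphs were written before their members' values were looked at but after the naming of probe sets was known, and the test on hybridisation controls was chosen after its result was seen. Of 19 such lists, 7 had a median log2 ratio outside the central 95% of matched random lists. Several share members with the fixed lists, and that for xylan backbone and chain length holds the same 4 probe sets as the fixed xylan list. The xyloglucan endotransglucosylases, which cut and rejoin xyloglucan in the wall, had a median log2 ratio of 0.25 over 8 members, at percentile 97.8, with 6 higher in sample 2. XTH16 had 52.5 in sample 1 and 92.9 in sample 2. The cellulose synthase-like glycan synthases had a median of 0.29 over 8 members, at percentile 99.4, but at a signal of 50 on both arrays it was 0.12, at percentile 89.0. Nuclear photosynthesis genes had a median of 0.13 over 14 members, at percentile 99.0, and 12 were higher in sample 2, among them PORB, a chlorophyll synthesis gene, with 150.6 and 205. With the limit from the seed, pollen and flower list, which rests on 1 probe set, that median was 0.09, at percentile 95.5 and so inside the central 95%, and at a signal of 50 on both arrays it was 0.23, at percentile 99.98. The 69 chloroplast-encoded probe sets went the other way, with a median of -0.13, at percentile 0.01, and 57 lower in sample 2. After loess correction that median was -0.07, at percentile 0.04. Cold and dehydration genes had a median of -0.36 over 9 members, at percentile 0.03, with 7 lower in sample 2, including XERICO at 323 and 242. This list shares COR15A, COR15B and COR47 with the fixed list for heat, cold and drought, so it is no independent result. Likewise, the cellulose synthase-like list shares CSLC04 with a fixed list, the defence list PDF1.2, and the nuclear photosynthesis list RCA and LHCB4.1. Defence genes had a median of 0.38 over 12 members, at percentile 98.9, from mostly dim probe sets, of which 6 passed the limit from all Bacillus controls. Of the 12, 9 were higher in sample 2, with SAG101 at 26.4 and 59.7. The 3 lower ones were the defensin genes PDF1.2, at 10.8 and 3.4, PDF1.2b and PDF2.1, while the defensin genes PDF1.4 and PDF2.5 were higher. After adding 16 before log2 the median of the defence genes was 0.22, at percentile 99.7. The wall acetylation family had -0.13 at percentile 1.47, which became -0.07 at percentile 12.8 after loess correction, and percentile 12.7 after quantile normalization, 4.54 at 2 times the limit, 6.04 with all Bacillus controls and 13.9 at a signal of 50.

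The tubulins and expansins lay inside the central 95%. The 7 tubulin probe sets were above the limit, against a median of 6 in random lists of that size. They had a median log2 ratio of 0.00, with TUA6 at 1179 and 1126. The expansins had a median of -0.02 over 15 members, and EXLA2 was the member that differed by 2-fold. Autophagy and vacuolar processing genes, which act in programmed cell death among other processes, were above the limit for all 13 members. Random lists of that size had a median of 11 above the limit. GAMMA-VPE, a vacuolar processing enzyme gene, had 2454 and 2142, and 11 of the 13 were lower in sample 2. Their median log2 ratio of -0.13 lay at percentile 2.53, just inside the central 95%, but at 1.83 after quantile normalization, 2.08 after loess correction, 2.12 at 2 times the limit, 1.57 after adding 16 and 1.72 with all Bacillus controls. It stayed inside, at 2.71, with plainly named probe sets alone and, at 2.87, at a signal of 50. PYK10, a glucosidase gene of endoplasmic reticulum bodies, had 769.6 and 984. The lignin-related glucosidase genes BGLU46 and BGLU47 had 327 and 413, and 102 and 133. Of 32 pollen, egg and endosperm probe sets, 16 were above the limit on both arrays, 6 with the limit from all Bacillus controls, and 0 at a signal of 50.

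CML37, GRX480 and EXLA2 were named above for being among the largest differences toward sample 2, so their direction is no support for a touch pattern. In the calcium and touch list, 7 of 11 members had higher signals in sample 2, CML37 and CML38 among them. ORA47, CML23, CML30 and CML41 had lower ones. The list had a median log2 ratio of 0.12, at percentile 96.1, inside the central 95% (percentile 99.7 at a signal of 50). A candidate explanation is that the samples differed in their rapid response to handling or wounding. Of 48 other rapid wound and touch response genes, listed before any of their values were seen, 23 were measured and 21 of these were above the limit on both arrays, with a median log2 ratio of 0.32 at percentile 100 and 15 higher in sample 2, such as PUB23 with 27.9 and 70.8, whereas AT4G27280 had 1824 and 1542. After loess correction for signal the median was 0.30, still at percentile 100, and at a signal of 50 on both arrays it was 0.17 over 12 members. The random lists come from the same bins of signal, so a bias shared at like signal is largely in them before loess. The correction is therefore no separate test of such a bias. The hypothesis stays open: such genes are regulated together, there was 1 sample on each side, and the labels record nothing about handling or harvest.

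The lower signals of LTI30, COR47 and XERICO in sample 2 might reflect a difference in response to abscisic acid or dehydration. A list of 30 other such genes, written before any of their values were seen, held 5 measured members, and 4 were above the limit. Their median log2 ratio was 0.16, at percentile 86.7, with 3 higher in sample 2, which goes against that explanation. The test rests on 4 members.

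The hybridisation controls, bacterial and phage transcripts added to the hybridisation mix, were lower in sample 2 for all 18 probe sets, with a median log2 ratio of -0.78 and a range from -1.63 to -0.44. A loss of bright signal on that array could lower them, but after loess correction the median was -0.75, at percentile 0 of 10000 medians of 18 plant probe sets of like signal, the central 95% of which lay between -0.09 and 0.10. A smaller share of controls in the hybridisation mix was not tested. No biological explanation was tested, since the controls are not plant transcripts.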
